A study of Arabidopsis thaliana with 7 samples.

How the data were processed

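HY5-YFP ChIP-seq was analysed in 6 libraries, 3 from plants kept in blue and 3 from plants kept in red light. All plants belonged to the Wassilewskija accession of Arabidopsis and carried the hy5-ks50 mutation and the HY5-YFP fusion, per the labels. Per the labels' protocols, chromatin was fixed with formaldehyde, sonicated and pulled down with beads that bind green and yellow fluorescent protein, and libraries were amplified by PCR. The mock was made, per the labels' protocols, from the pooled blue light samples with beads lacking the antibody, and it enters only through values in the peak lists of the other libraries. An input sample named in the protocol was not analysed here. Plants expressing the fusion were the only ones examined, so binding to genes such as GI or CHS refers to HY5-YFP and not to HY5 in plants without the transgene. Pull-down with the antibody from plants without the fusion was not examined, so signal that does not depend on HY5-YFP is not excluded.

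Each library has a peak list. Per the file headers, the authors called peaks in each library alone with the HOMER program findPeaks in its factor style, with the mock as control. HOMER was of version 4.9 and the genome build TAIR10, per the submitters' processing notes, and the aligner is not given in the sources used here. Per the file headers, a peak needed a 4-fold excess over the mock and over its 10000 bp surroundings, a Poisson p-value of at most 0.0001 in both and a false discovery rate of 0.001. The width of the peak window follows an estimated fragment length per library, per the file headers: 347, 348 and 340 bp in blue and 549, 306 and 312 bp in red light replicates 1 to 3. The fragment length of red light replicate 1 was estimated at 548 bp against 188 to 226 bp in the other libraries, so its tag numbers come from wider windows. The deposited signal of a peak is its tag number scaled by the authors to 10 M (1 M is 1e6) tags of the library, per the file headers. Multiplied by the library's total, it gave whole tags within 0.1 for 100% of the peaks of every list. The lists also hold the authors' unscaled mock signal, their fold over the mock and over the surroundings, the p-value of each and the caller's score, of which the mock signal was used throughout, the fold over the mock for a filter and both folds for library medians, and the p-value and score were not used.

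Peaks of the 6 lists were joined into sites with bedtools 2.31.1 where they shared at least 1 bp. A site counted as called in a library with a peak in it, and 1 pair of site and library held more than 1 peak, of which the highest was taken. The join gave back all 3000 sites of a simulated set, whose sites stood too far apart to touch, so the joining of close sites was not tested. A consensus site was called in at least 2 of 3 libraries of a light. Peak numbers and shares were compared between lights with exact two-sided permutation tests over the 10 splits of 6 libraries, which cannot go below p = 0.1. Peak lists were compared by the Jaccard index over sites.

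Tags were compared with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3 on log2(tags per 10 M + 1) at the 3557 sites called in all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 folds are on this scale. Sites without a peak in a library have no value there, so sites lost from the red lists do not enter this test. On data simulated for these 3557 sites with the real depths, limma recovered 100% of sites changed by 1 and 92.0% of those changed by 0.5 (log2), with 5 false calls. When 1 simulated library was raised by 0.6, as a wider window does, it recovered 71.0% and 11.0%, and 100% and 89.0% after each library was centred on its median.

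Gene lists were fixed before the data were examined: 9 lists of genes of the clock and of light, plastid, growth, hormone and cold responses, and 3 control lists of housekeeping, seed and floral genes, with 196 genes in all. All 196 loci were found in the RefSeq gene table of assembly TAIR10.1, which was used for gene names and neighbours alone. Positions are those of the peak lists. The table carries no strand, so the planned window around the start of a gene was replaced by a window of 1500 bp outward and 500 bp inward of either gene end, and a site can lie inside another gene, as that of RVE8 lies inside AT3G09590. Classes of location were reduced to inside or between genes for the same reason. A search for the ACGT-core motif that HY5 binds needs a genome sequence and was not run. Lists were compared with all other protein-coding genes by Fisher's exact test, lights within a list by the exact McNemar test, and list medians of the log2 fold by a permutation test with 100000 draws, each adjusted over the lists. The sites were also shifted 200 times around each chromosome at random.

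The named genes followed a rule fixed before the data were examined. It takes every clock gene with a consensus site, the 4 genes of each other list with the highest tags over all 6 libraries (0 where no peak was called) and those with a consensus site in a single light, the 10 highest sites called in all 3 libraries of a light and none of the other, the 10 highest sites called in all 6, and the 5 smallest adjusted p-values of limma in each direction. A site picked through a list or family is named after that gene, even where another gene end is nearer, as at PHYB, SIG5, IAA29, DFR, HFR1 and PRR7. Other sites are named after the gene with the nearest end. CHS, HFR1, DFR, COP1, SPA4, UGT78D2 and GUN5 are further members of the lists, and they were picked after their values were seen. Alternatives were peaks at least 8-fold over the mock, equally long lists, each library left out, other joins, consensus rules, gene windows, pseudocounts of 0.1 and 5, centring on library medians, the sites above the median height, and the replicate number as a block. Tags divided by window width, centring without red light replicate 1, removal of a trend with height, and equally long lists without red light replicate 1 were added after seeing the data. Replicates were checked for duplicates: tag numbers of pairs within a light differed by 1.42 to 2.80 times the counting noise (chi-square per degree of freedom), so all 6 libraries were kept.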

Results

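HY5 is a bZIP transcription factor that promotes light-dependent development of seedlings. Its binding to the genome was mapped by ChIP-seq, in which chromatin fragments are pulled down with the bound protein and sequenced. The Arabidopsis plants were of the Wassilewskija accession, carried the hy5-ks50 insertion mutation and expressed HY5 fused to the yellow fluorescent protein (HY5-YFP). Whole plants 10 days old were fixed after 52 hours in blue or in red light of 15 µmol per square metre and second. There were 3 biological replicates per light, and 1 mock sample that was made from the 3 blue samples with beads lacking the antibody. The sequenced depth was 11.7, 10.1 and 7.99 M tags in blue light replicates 1, 2 and 3, and 10.6, 11.5 and 11.9 M in the red light ones. The series title puts the part of HY5 in passing blue light signals to the circadian clock as the question, so the comparisons were blue against red light and clock genes against other genes.

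In both lights the highest peak of every library lay at HY5 itself, with 9184 ± 334 tags per 10 M in blue light (SD, n = 3) and 13514 ± 4628 in red light (SD, n = 3). The next highest sites called in all 6 libraries lay beside AT3G22440, with 3481 ± 59.8 tags in blue and 2544 ± 501 in red light, and beside EDD1, with 2770 ± 96.7 and 2656 ± 955. AT1G01335, AT1G48840, GSTU15, which encodes a glutathione transferase, AT2G46420, FC1, which encodes a ferrochelatase, RPT2, a protein of phototropin signalling, and AFP3 completed the 10 highest sites. Among the other genes chosen beforehand, F3H of flavonoid synthesis (1756 ± 57.8 tags in blue, 1402 ± 357 in red), SIG5, a plastid sigma factor (2083 ± 41.2 and 1770 ± 396), ELIP1, an early light-induced protein (1548 ± 30.3 and 718 ± 290), and SPA1, a partner of COP1 (1513 ± 77.5 and 1341 ± 396), had the highest peaks in blue light (SD, n = 3 each).

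Blue light libraries held 8724, 8524 and 8888 peaks and red light libraries 4027, 5672 and 5441. The mean was 8712 ± 182 in blue and 5047 ± 891 in red light (SD, n = 3), a ratio of 1.73. All 3 blue values lay above all 3 red ones, and the exact two-sided permutation test gave p = 0.1, the smallest p that 3 against 3 libraries allow. Peaks took up 25.4% ± 0.493 of the tags in blue and 13.9% ± 1.75 in red light (SD, n = 3; exact permutation p = 0.1). Candidate peaks before the comparison with the mock numbered 23373 ± 759 in blue and 21069 ± 3648 in red light, and that comparison removed 42.3% ± 2.07 of them in blue and 59.1% ± 0.810 in red light. Red light replicate 1 had 16857 candidates, while red light replicates 2 and 3 had 23218 and 23131, within the blue range of 22701 to 24196. The mock came from blue light plants alone, and red light replicate 1 was called with wider peak windows than the other libraries.

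**Figure D1:**
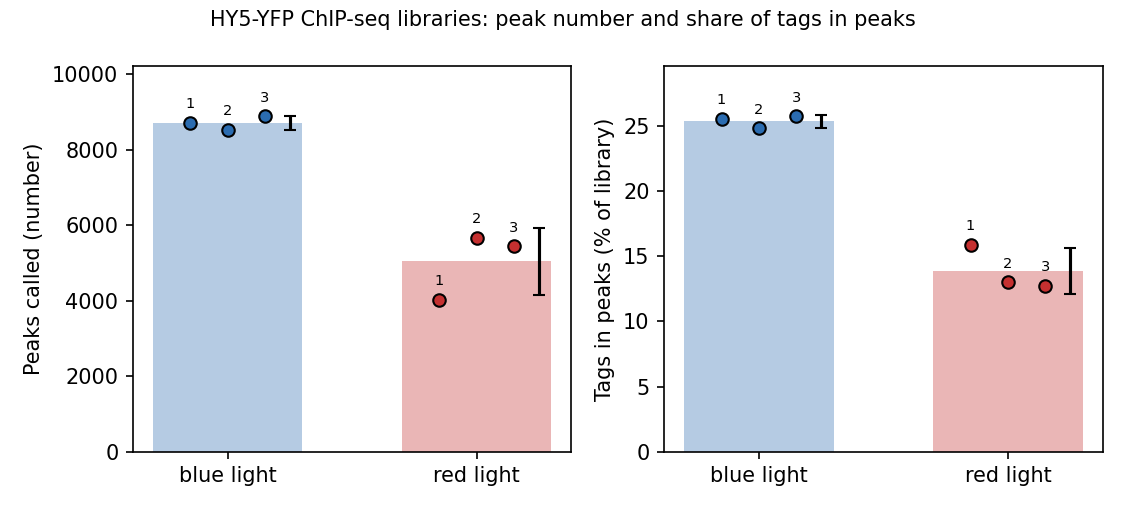
Peaks called (left) and percent of the library's tags in peaks (right) for the HY5-YFP libraries; bars are means, error bars SD, and points the 3 replicates of each light with their numbers. The blue light libraries hold 8524 to 8888 peaks and the red light ones 4027 to 5672.

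Joined where they overlapped, the peaks of the 6 lists made 10233 sites, of which 3557 were called in all 6 libraries. HY5, GI, LHY, TOC1, CHS, which encodes chalcone synthase, COP1, an E3 ubiquitin ligase that marks HY5 for degradation, and PHYB, the main red light photoreceptor, were among the genes with such a site. A consensus site, called in at least 2 of 3 libraries of a light, was found 8633 times in blue and 5043 times in red light. Of the red consensus sites 98.7% were blue consensus sites too, while 57.6% of the blue ones were red ones. Peak lists were more alike within a light than between lights, with a mean Jaccard index (shared sites over all sites of a pair) of 0.744 within and 0.552 between (exact permutation p = 0.1). The mean was 0.815 over the blue pairs and 0.672 over the red pairs. Red pairs ranged from 0.625 to 0.753, and pairs between lights reached 0.618. Unequal list lengths limit this index, and with equally long lists the difference was 0.0883 instead of 0.192. All 6 lists were called against the same mock, and its effect on the overlaps was not tested.

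Clock genes had HY5-YFP sites in both lights. Of the 30 genes on the circadian clock list, 29 had a blue consensus site and 23 a red one, against 43.2% and 26.4% of 27432 protein-coding genes (Fisher's exact test, adjusted p = 5.68e-09 and 1.53e-07 over 12 lists). The highest clock site lay between AT1G22760 and GI (AT1G22770), a gene of photoperiod timing, at positions 8060553 to 8061101 of chromosome 1, with 1077 ± 25.4 tags in blue and 1010 ± 211 in red light (SD, n = 3). LUX, ELF3 and ELF4, which form the evening complex, had 905 ± 86.7, 420 ± 32.9 and 680 ± 59.7 tags in blue and 672 ± 164, 295 ± 72.4 and 400.4 ± 116 in red light. The morning genes CCA1 and LHY had 305.7 ± 19.9 and 602 ± 3.65 tags in blue and 235 ± 60.1 and 426 ± 65.8 in red light. The pseudo-response regulators PRR9, TOC1, PRR7, PRR3 and PRR5 ranged from 204 tags (PRR5) to 651 tags (TOC1) in blue light.

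The other clock genes with a consensus site in both lights were LNK3, BOA, FKF1, LNK4, LNK1, CHE, RVE4, RVE1, LWD2, TIC, LKP2 and RVE2, with blue means from 160 tags (LKP2) to 874 tags (LNK3). A consensus site in blue but not in red light was found at RVE8 (273 ± 25.3 tags in blue), CDF1 (277 ± 28.0), LNK2 (215 ± 5.84), LWD1 (244 ± 12.6), RVE7 (184 ± 13.8) and RVE6 (97.9 ± 2.83, n = 2). RVE8 and LNK2 each had 1 red library with a peak, and the others had none. No clock gene had a consensus site in red light alone. The exact McNemar test of these 6 against 0 genes gave p = 0.0312, or 0.188 adjusted over 12 lists, and of all genes with a blue consensus site 60.7% had a red one against 79.3% of the clock genes (Fisher's exact test, adjusted p = 0.541). ZTL, which encodes a blue light receptor of the clock, had no consensus site. In 200 circular shifts of all sites along their chromosomes, the clock list reached at most 16 genes with a blue site and 13 with a red one. Such shifts also take sites away from gene ends, so they set a low bar. The photoreceptor list, which did not pass Fisher's exact test, lay above every shift too (7 genes with a blue site against at most 6). Against the 36 genes of the control lists, of which 19 had a blue and 12 a red consensus site, Fisher's exact test gave adjusted p = 0.000477 in blue and 0.005 in red light. Genes of a list are not independent of each other, so these p-values are descriptive.

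**Figure D2:**
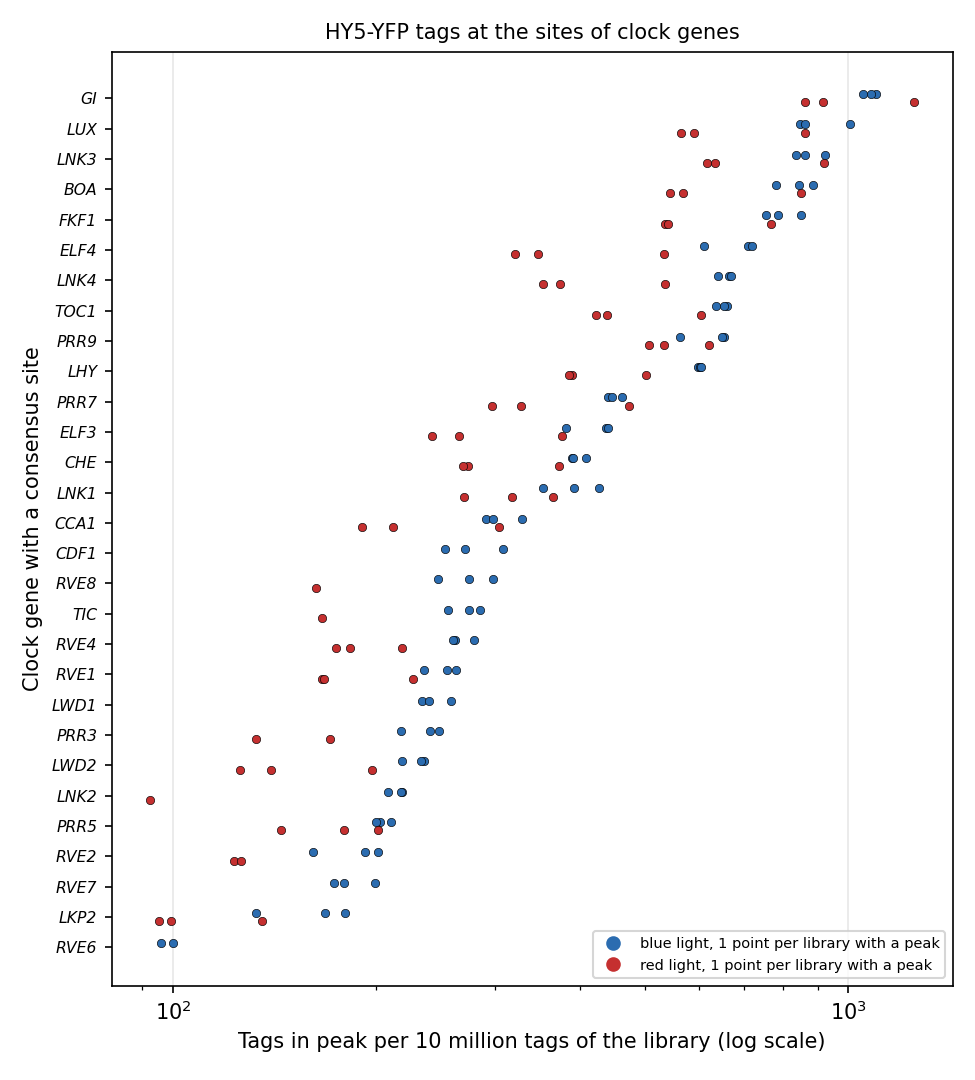
Tags per 10 M (log axis) at the highest site of each of the 29 clock genes with a consensus site, 1 point per library with a peak, blue and red points for the lights. GI has the highest mean in blue light, 1077 tags, and CDF1, LWD1, RVE7 and RVE6 have no red point.

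Regulators of photomorphogenesis and genes of chlorophyll and plastid formation had more sites in both lights than all protein-coding genes. Of 27 photomorphogenesis regulators 20 had a blue and 15 a red consensus site (Fisher's exact test, adjusted p = 0.00899 and 0.00891), led by HY5, SPA1, SPA3 and BBX28. Of these, RUP1, FHL, DET1, FAR1 and BBX30 had a consensus site in blue light alone. RUP1, a repressor of the UV-B receptor UVR8, had 744 ± 28.6 tags in blue light and no red peak, and BBX30 had 500.1 ± 5.92 tags and 1 red peak of 195 tags. Of 16 chlorophyll and plastid genes 13 had a blue and 10 a red site (adjusted p = 0.015 and 0.0102), led by SIG5, ELIP1, PSY, which encodes phytoene synthase, and ELIP2. GUN4, CRD1 and CHLM of chlorophyll synthesis had a consensus site in blue light alone, GUN4 with 508 ± 14.3 tags. Against the 36 control genes neither list passed Fisher's exact test (photomorphogenesis adjusted p = 0.352 in blue and 0.367 in red light, chlorophyll 0.306 and 0.315). The chlorophyll call ended with windows of 3000 bp outward (adjusted p = 0.202 in blue and 0.114 in red light) and, in red light, with peaks at least 8-fold over the mock (0.173).

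Of 19 photosynthesis antenna and Rubisco genes 14 had a blue site (adjusted p = 0.0287) and 6 a red one (adjusted p = 0.606), led by LHCB4.1, LHCA4, LHCB1.4 and LHCB1.5. LHCB6, LHCB1.1, LHCB1.2, LHCB2.2, RBCS1A, RBCS1B, RBCS2B and RBCS3B had a consensus site in blue light alone, with blue means from 145 tags (LHCB2.2) to 373 tags (LHCB6), and no gene of the list in red light alone. This difference gave p = 0.00781 in the exact McNemar test and 0.0938 adjusted over 12 lists. More genes had a blue than a red consensus site over all protein-coding genes too, so this test does not single out the list. Of its genes with a blue site 42.9% had a red one, against 60.7% of all genes with a blue site (Fisher's exact test, adjusted p = 0.541). Neighbouring copies such as LHCB1.1 with LHCB1.2 and RBCS1B with RBCS2B were counted by the same site, and tags between near-identical copies are uncertain. With peaks at least 8-fold over the mock the antenna list had 4 blue genes (adjusted p = 1), and with windows of 3000 bp outward its adjusted p was 0.202. Against the 36 control genes the adjusted p was 0.356 in blue light.

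Of 14 PIF and elongation genes 10 had a blue (adjusted p = 0.132) and 8 a red site (adjusted p = 0.0433), led by IAA29 (1068 ± 42.0 tags in blue, 988 ± 176 in red), PIF5, PIF6 and PAR2, with a consensus site of PIF8 and ATHB2 in blue light alone and 1 red peak at each. With peaks at least 8-fold over the mock the red count was 2 (adjusted p = 0.856) and the blue one 9 (0.00309), and the red call also ended with narrower (0.292) and wider windows (0.103). Against the 36 control genes the PIF list did not pass (0.614 in blue and 0.446 in red light). Sites of flavonoid genes (12 blue and 10 red of 22), photoreceptors (7 and 6 of 11), hormone genes (7 and 5 of 13) and cold genes (5 and 4 of 8) did not pass the test in either light. The highest flavonoid sites lay at F3H, MYB12, MYB11 and FLS1, and CHI and C4H had a blue consensus site alone. The photoreceptors were led by PHOT2, CRY3, PHYB and PHYC, and CRY1 had a blue consensus site alone and 1 red peak. Over all 6 libraries the hormone genes ABI5, GAI, ERF11 and IAA14 were highest, with a consensus site of GA2OX1 and IAA7 in blue light alone. CBF3, a cold regulator, had 1278 ± 32.5 tags in blue and 854.8 ± 225 in red light, followed by COR47, KIN1 and CBF2, with a consensus site of CBF2 and COR78 in blue and of CBF1 in red light alone. CBF2 and COR78 each had 1 red peak, and CBF1 had 1 blue peak of 498 tags, above its red ones. Some alternatives did call these lists: flavonoid genes passed in both lights with peaks at least 8-fold over the mock (adjusted p = 0.00309 and 0.0162), with equally long lists (0.0242 and 0.0284) and by nearest gene end (0.0244 and 0.00711). Hormone genes passed in both lights by nearest gene end (0.0015 and 0.0334), photoreceptors and cold genes in 1 of 16 alternatives in each light.

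The control lists did not pass the test with the main settings, and housekeeping genes passed in blue light in 2 of 16 alternatives (adjusted p = 0.037 with narrower windows and 0.0244 by nearest gene end). Housekeeping genes had 10 blue and 7 red sites of 15 (adjusted p = 0.147 and 0.143), led by UBQ11, GAPC1, UBQ10 and ACT2, with a consensus site of PP2AA3, EF1A-A1 and GAPC2 in blue light alone. Seed storage and oil body genes had 6 and 4 of 11 (adjusted p = 0.577 and 0.54), led by sites beside CRA1, CRB, OLEO1 and EM1, with a consensus site of EM6 and CRB in blue light alone and 1 red peak at CRB. Floral organ genes had 3 and 1 of 10 (adjusted p = 0.577 and 0.54), namely AP1 in both lights and SEP2 and SHP1 in blue light.

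**Figure D3:**
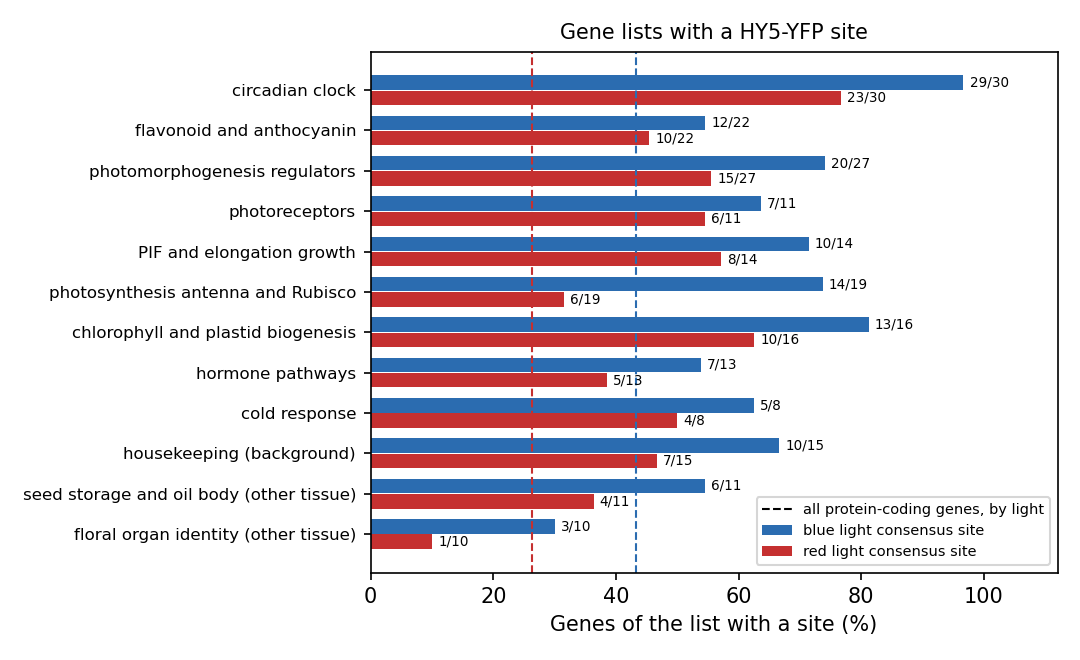
Percent of the genes of each fixed list with a consensus site in blue and in red light, with the number of genes beside each bar; dashed lines give the share of all protein-coding genes, 43.2% in blue and 26.4% in red light. The clock list has the highest share in both lights, 29 and 23 of 30 genes.

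RUP1 had the highest site that was called in all 3 blue and in no red library, between AT5G52240 and AT5G52250 at positions 21215829 to 21216237 of chromosome 5. It was followed by sites beside AT1G64500 (694 ± 35.8 tags), AT5G64780 (619 ± 40.0), SETH6 (613 ± 15.5), AT1G70000 (579 ± 22.9), AT3G59390 next to GUN4 (508 ± 14.3), AT5G47610 (464 ± 43.6), AT1G64260 (459 ± 17.9), SDR2 (439 ± 21.1) and AUF1 (438.0 ± 18.6; SD, n = 3 each). There were 1521 such sites, and 1 site called in all 3 red and no blue library, beside SQE3 at positions 17743025 to 17743573 of chromosome 4 (147 ± 41.2 tags in red light, SD, n = 3). In the other 9 splits of the 6 libraries into 3 and 3, at most 50 sites were called in all libraries of a side and none of the other, and the real split was 1 of 10. Each of those 9 splits holds both lights on either side, and most red sites were blue sites too, so few such sites follow whatever the cause. Sites in all 3 blue and no red library had a median of 157 tags in blue light, and those called in all 6 had 359. Among the 1855 highest of the sites called in all 3 blue libraries, 28 lacked a red peak. With equally long lists, the 4027 highest peaks of each library, the counts were 233 and 85. At RUP1 the mock held 52.0 tags, against library medians of 20 to 31 over the sites called in all 6. A peak needed a 4-fold excess over the mock, so red tags below that bar at RUP1 would not have been called.

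At the 3557 sites called in all 6 libraries, tags were higher in blue light at ELIP2, with 886 ± 19.2 in blue and 279 ± 86.2 in red light (log2 fold 1.71, SE 0.21), and at AT4G26190, AT4G36530, AT1G75490 and PyrD, with log2 folds of 1.67 to 1.79 (limma, adjusted p at most 1.32e-12). Of the listed genes, SPA4 (log2 fold 1.19), UGT78D2 of flavonoid glycosylation (1.18), ELIP1 (1.18), GUN5 (1.29), COP1 (0.98), HFR1 (0.85), DFR (0.85) and CRY3 (0.84) passed the limma test too. DAA1, at positions 23801850 to 23802398 of chromosome 1, was the site with higher tags in red light (log2 fold -0.54, SE 0.22, limma adjusted p = 0.035). In all, 1846 sites were higher in blue and 1 in red light by limma at an adjusted p under 0.05 (4 were higher in red light at an unadjusted p under 0.05), and the median log2 fold of all sites was 0.48.

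This count rested on the scaling and on red light replicate 1, whose wider window collects more tags. Without that library 4525 sites of 4615 were higher in blue and 6 in red light, and without any other library 140 to 220 were higher in blue and 0 in red light. The library medians differed by 0.53 (log2) between lights, so changes relative to the median were also computed. With each library centred on its median, 283 sites were higher in blue and 421 in red light relative to the median. Centring removes the shift common to all sites, whatever its cause. A centred call toward red light therefore does not by itself mean more tags in red light.

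Relative to the median, clock genes went both ways. Over all tested sites 7 of the 20 clock sites called in all 6 libraries (ELF4, LNK4, LHY, ELF3, RVE4, LWD2 and LKP2) were higher in blue light by limma without centring, and 3 when adjusted over the list alone. After centring, ELF4 was higher in blue light (0.27 above the median, limma adjusted p = 0.00817). GI (-0.42, adjusted p = 6.09e-07), PRR9 (-0.36, adjusted p = 0.000366), LNK3 (-0.23, adjusted p = 0.00549) and PRR5 (-0.29, adjusted p = 0.0484) lay toward red light relative to the median. Without centring these sites had more tags in blue light, with log2 folds of 0.11 at GI, 0.17 at PRR9, 0.30 at LNK3 and 0.23 at PRR5, and none passed. With a trend with height removed, the calls at LNK3 (adjusted p = 0.0587) and PRR5 (0.147) ended. That made 5 centred calls over all sites and 7 adjusted over the list alone. The median log2 fold of the clock sites was 0.42 against 0.48 for the other sites (permutation p = 0.129, adjusted p = 0.431).

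Other listed genes also lay on both sides of the median after centring. Relative to it, SPA4 (0.67), UGT78D2 (0.65), ELIP2 (1.18), ELIP1 (0.65), GUN5 (0.76) and COP1 (0.45) were higher in blue light, and HY5 (-1.03), PHYB (-0.73), MYB12 (-0.44), IAA29 (-0.40), SPA1 (-0.31) and SIG5 (-0.27) in red light (limma, adjusted p at most 0.000267 each). Of the latter, only HY5 (-0.51) and PHYB (-0.20) had log2 folds toward red light without centring, and neither passed. MYB12 (0.091), IAA29 (0.13), SPA1 (0.21) and SIG5 (0.26) had more tags in blue light. With a trend with height removed, the calls at SPA1 (-0.11, adjusted p = 0.204) and SIG5 (0.016, adjusted p = 0.872) ended, and the log2 fold was -0.14 at HY5, -0.28 at MYB12 and -0.27 at IAA29. Of the lists tested, the flavonoid and chlorophyll lists had the largest medians of the uncentred log2 folds, 0.65 and 0.63. They did not differ from the other sites after adjustment (permutation p = 0.0147 and 0.0276, adjusted p = 0.138 for both). None of the tested lists passed. The cold and floral lists, with 2 and 1 sites called in all 6 libraries, were not tested.

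**Figure D4:**
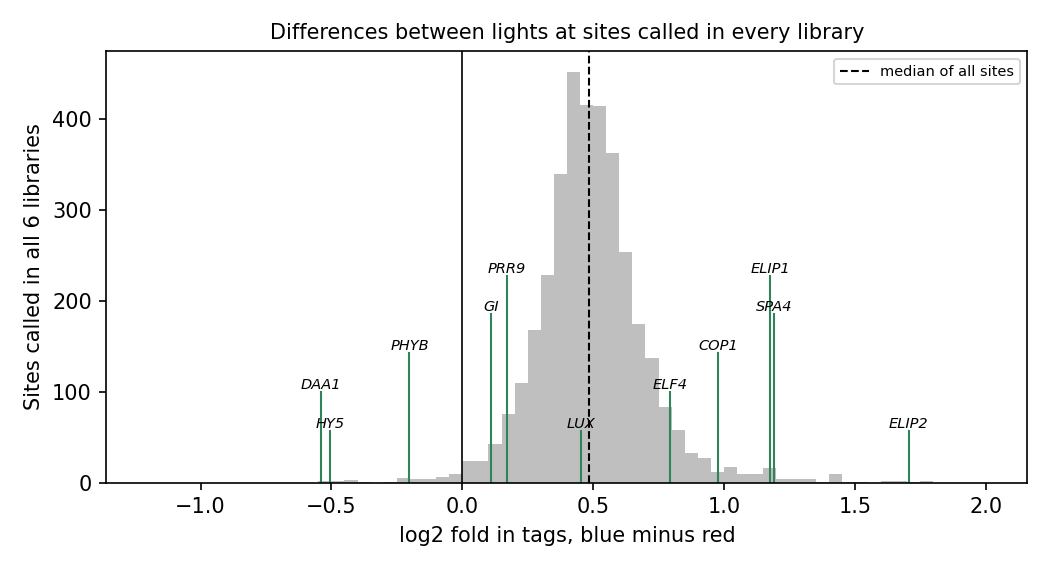
Log2 fold in tags between lights (blue minus red, no centring) at the 3557 sites called in all 6 libraries, as a histogram with 11 genes marked. The median is at 0.48, and GI (0.11), PHYB (-0.20) and HY5 (-0.51) lie below it while SPA4 (1.19) and ELIP2 (1.71) lie above it.

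The centres of the sites lay more often between protein-coding genes, as at GI, PRR9, LHY and CCA1, than inside them, as at SPA4, ELF3, UGT78D2 and HY5 (positions 3594787 to 3595335 of chromosome 5). Peak centres lay inside a protein-coding gene in 43.5% ± 0.354 of blue and 43.1% ± 0.577 of red light peaks (SD, n = 3; exact permutation p = 0.5). Of all 10233 sites 44.1% had their centre inside a gene, against 56.3% to 67.6% when the sites were moved by 500 to 10000 bp to either side. The median distance from a site's centre to the nearest gene end was 156 bp.

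Fewer tags at these sites in the mock than in the HY5-YFP libraries were fixed by the calling, which required a 4-fold excess over the mock. At GI it had a median of 56.5 tags, at LUX 41.0, at LHY 42.0 and at RUP1 52.0, in a library of about 6.84 M tags, against a median of 18 to 31 over the peaks of each list. HY5 had the highest mock tags, 683.5, and its median fold over the mock, 10.4, was near those of GI (12.7), LUX (12.8), LHY (8.58) and RUP1 (9.99). Of 10 groups of the sites called in all 3 blue libraries by height, the lowest had a median of 11.7 mock tags and the highest 38.7, and the requirement of a 4-fold excess over the mock limits mock tags at low sites.

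**Figure D5:**
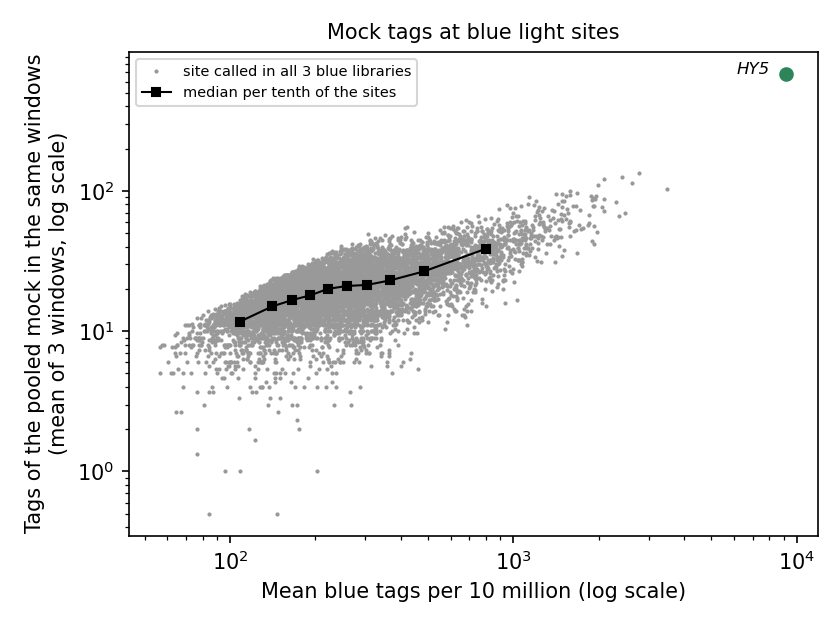
Tags of the pooled mock against mean blue tags per 10 M at the 7422 sites called in all 3 blue libraries, both axes logarithmic; squares are medians of 10 groups of sites by height. HY5 stands apart with 686 mock tags (mean of the 3 blue windows), and the next highest site has 133.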

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

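The tests of explanations here were all chosen after the results were seen. HY5 drew attention through the mock, which was the control of every peak list and does not enter the tags: its median over the 6 windows at HY5 was 683.5 tags, and its lowest ratio to the median mock tags of the same list was 26.2. No other site called in all 6 libraries had more than 5 times that median in every list.

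HY5 stood out by its mock tags, while its fold over the mock (8.88 to 15.9) did not, and its uncentred log2 fold between lights passed (-0.24, limma, adjusted p = 8.42e-17) without red light replicate 1 and not with all 6 libraries (-0.51, adjusted p = 0.102). Relative to the library medians HY5, like 421 sites in all, was lower in blue than in red light by a log2 fold of -1.03, and of -0.93 without red light replicate 1, which argues against the wide window of that library as the cause. Once a trend with height was removed, the fold was -0.14 (limma, adjusted p = 0.00219), but no other site is near its height, so the trend is poorly set there. Bound fragments carried into the mock may add to its tags: the line through the other sites called in all 3 blue libraries predicts 322 mock tags and 686 were found, yet the line ends at 3481 blue tags and HY5 has 9184, so this stays open. Extra copies of HY5 in the transgene cannot be told apart from it, since mock tags per bp were 3.11 times as dense in the narrowest window as in the outer part of the widest, 11.9 times the genome mean even there, and the extent and number of the inserted copies are not given.

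More peaks, and higher ones at genes such as ELIP2, SPA4 and COP1, were found in blue light. Deeper sequencing of the blue libraries is argued against by 7 of 9 pairs of a blue and a red library, in which the blue library had fewer tags and more peaks, and the wide window of red light replicate 1 by the ratio of 1.57 in peak number without it. A mock made from blue chromatin alone does not enter the tags, which differed by 0.53 in the median log2 at the sites called in all 6 libraries. Those sites were picked by calls against that mock, so its effect on this difference was not tested. For peak number the mock stays open too, since candidate peaks before the comparison with it differed by a ratio of 1.11. Red light replicates 2 and 3 had 23218 and 23131 of them, within the blue range of 22701 to 24196. Weaker pull-down in red light is in line with the loss of low sites: a site with all 3 red peaks was higher in blue light than a site with none with a chance of 0.908. Less HY5-YFP on chromatin in red light, the biological explanation, predicts the same and the larger share of tags in peaks in blue light (by 11.5 percentage points), and the design cannot tell it from pull-down.

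Sites departed from this common shift in both directions after centring, such as ELIP2, SPA4 and ELF4 toward blue and GI, PRR9, PHYB and MYB12 toward red light. A single factor between the lights is argued against by these 704 sites of 3557 tested. A trend with height is argued against as the whole cause by 551 of the 704 sites, called in the same direction without it (282 of 283 toward blue and 269 of 421 toward red light, while LNK3 at adjusted p = 0.0587 and PRR5 at 0.147 were not), and the wide window of red light replicate 1 by 592 of 701 sites called without that library. An effect of light colour on binding at these genes may remain, as a hypothesis found and tested on the same data. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real split gave 1846 and 1 sites, 283 and 421 after centring, and the highest of the others gave 0 in each case. The real split alone, 1 of 10, reached each count. Every other split holds both lights on either side, so a difference between lights, whatever its cause, widens the spread there. Few calls in them are therefore no evidence on the cause.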

How the results depend on the processing

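The alternatives were listed before the data were examined, except the 4 named as added in the methods. Every alternative that gives a value kept more peaks in blue light (ratio 1.57 to 2.38, the highest with peaks at least 8-fold over the mock) and 23 to 30 clock genes with a blue site. With that filter clock genes with a red site fell to 13, and the mean Jaccard index within lights exceeded that between lights by 0.290. Sites in all 3 red and no blue library were then 0, and sites higher in blue light 533. With equally long lists sites in all 3 blue and no red library were 233, the reverse 85, and sites higher in red light 2. The share of red consensus sites in the blue set was 86.7%, and the difference in the Jaccard index 0.0883. The ratio of peak numbers is fixed with such lists. Joining by centres gave 4 sites in all 3 red and no blue library, and leaving out each library 1 to 24. Leaving out each library gave 140 to 4525 sites higher in blue and 0 to 6 in red light, the highest without red light replicate 1. Sites above the median height gave 1065 and 2, tags per window width 3420 and 8, and centring 283 and 421. Centring without red light replicate 1 gave 392 and 494, and removal of a trend with height 352 and 269. Equally long lists without red light replicate 1 gave 3783 and 6 of 3809 sites. The causes of these changes were not tested, apart from the shorter lists that the filters make.

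Replicate numbers are shared by the lights, and no label says whether they pair the samples. Deviations of libraries with the same number correlated at -0.037, -0.087 and 0.045, and not every library correlated best with its own number. The libraries were therefore treated as unpaired, though these values do not exclude a pairing. With the replicate block 1399 sites were higher in blue and 0 in red light, and the ratio of peak numbers was 1.75.

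Among the sites named by the rule that passed the threshold with or without centring, centring turned the sign of the log2 fold at GI (-0.42), PRR9 (-0.36), PRR5 (-0.29), LNK3 (-0.23), RVE4 (-0.045) and LHY (-0.018) of the clock list. It did so at MYB12 (-0.44), FLS1 (-0.20), F3H (-0.17), MYB11 (-0.022), SPA1 (-0.31), PHOT2 (-0.027), IAA29 (-0.40), PIF6 (-0.050), LHCB4.1 (-0.012), SIG5 (-0.27), PSY (-0.014) and ABI5 (-0.24). It also did so at UBQ10 (-0.029), UBQ11 (-0.012), ACT2 (-0.0044), CRA1 (-0.18), OLEO1 (-0.055), EDD1 (-0.41), AT2G46420 (-0.38), GSTU15 (-0.24), AT1G48840 (-0.21) and AFP3 (-0.18). Sites that passed in neither case turned as well, among them LUX (-0.075), TOC1 (-0.096), CCA1 (-0.12), FKF1 (-0.13), BOA (-0.15), PRR7 (-0.20) and PIF5 (-0.11). The cause is the shift of the library medians that centring removes. Leaving out each library gave a log2 fold at FC1 of -0.25 to 0.10, positive without red light replicate 1, and the cause was not tested. Over all alternatives 75 values of named sites newly passed the threshold and 150 no longer did.

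Over 16 alternatives the adjusted p of the clock list was 5.28e-10 to 3.01e-05 in blue and 1.95e-08 to 3.82e-05 in red light, that of the photomorphogenesis list stayed under 0.05 in both lights, and that of the antenna list in blue light ranged from 0.00017 to 1. Restricting to chromosomes 1 to 5 and removing crowded sites changed nothing, since they removed no site, and the motif search was not run. Depth and the calling thresholds, among them the 4-fold excess over the mock, limit the low sites of all 6 libraries. A site without a red peak did not pass these thresholds, and it is not shown to be unbound.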

Other observations

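The 19 families were chosen from gene symbols after the data were seen, and their tests were adjusted together within each light. Genes of other kinds with similar symbols were removed after a first run. Except for miRNA and tRNA loci, members are the genes with a matching symbol in the gene table. Families can therefore be incomplete, and shares are those of the matched genes. ERF factors, regulators of ethylene and stress responses, had 12 of 20 genes with a red site (60.0% against 26.4%; Fisher's exact test, adjusted p = 0.00987) and 14 with a blue one (70.0% against 43.2%, adjusted p = 0.0596). They were led by ERF5 (418 ± 8.64 tags in blue light), ERF71 (410 ± 3.58) and ERF8 (404 ± 39.0; SD, n = 3). Ribosomal protein genes had 25 of 40 with a blue site (adjusted p = 0.0596) and 13 with a red one (adjusted p = 0.511), led by RPL16A (622 ± 42.4) and RPL18 (458 ± 65.4). Before the removal the ribosomal family had passed in blue light.

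Cytochrome P450 genes had fewer sites than other protein-coding genes, 61 of 225 or 27.1% against 43.4% in blue light (Fisher's exact test, adjusted p = 4.15e-06) and 17.8% against 26.5% in red light (adjusted p = 0.014), close to the mean of 27.1% and 16.4% after 200 random shifts of the sites. CYP81G1 (1234 ± 66.0 tags), CYP98A3 of lignin synthesis (650 ± 14.3) and CYP71B34 with CYP71B35 at a shared site (625 ± 29.0) were the highest. MYB factors had fewer sites in blue light (37 of 120 or 30.8%, adjusted p = 0.034), within the range of the shifts (15.8% to 37.5%), and their lower share in red light (21.7% against 26.4%) did not pass (adjusted p = 0.505). Loci of miRNA and tRNA, whose windows are shorter than those of protein-coding genes, had blue sites in 23.0% and 31.5% against 43.2%. Random shifts gave a mean of 22.1% (at most 28.2%) for miRNA and 21.2% (at most 28.0%) for tRNA loci, so in blue light tRNA loci lay above every shift and miRNA loci within their range. In red light both lay within it, with 17.3% of tRNA loci (shifts at most 18.4%) and 14.7% of miRNA loci (at most 17.5%). Shifts also take sites away from gene ends, so lying above every shift is not particular to tRNA loci. In blue light WRKY factors (47.8%, shifts at most 41.8%) and ERF factors (70.0%, at most 55.0%) did so too.

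After centring, the sites with the smallest adjusted p toward blue light included those beside ELIP2, AT4G36530, AT1G75490, PyrD, FAF2, SNC1, an immune receptor gene, AT5G20740, AT4G26190, RD21A and HB40, with log2 folds of 0.80 to 1.26 above the median. Those toward red light were beside HY5, AT1G01335, AT2G06025, DRP5A, DAA1, WRKY41, AT4G03965, CUC1, a boundary gene of shoot organs, TAP46 and FC1, with log2 folds of -1.07 to -0.64 relative to the median (limma, adjusted p at most 9.42e-12 each). These genes were picked after their values were seen.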
